A study of Mus musculus with 16 samples.

How the data were processed

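Total RNA of mouse liver, extracted with Trizol and labelled with biotin per the labels, was measured on Affymetrix microarrays, 1 array per sample. The labels place the 16 arrays in 4 groups of 4, from 2 operations (partial hepatectomy, PHx, or sham) and 2 genotypes (Ppara fl/fl or PparaΔHep). All livers were taken 12 h after the operation. The labels do not say that each array came from a separate mouse, so p-values measure the spread between these arrays, part of which may be technical. Arrays are named here by group and by a number given in the order of the samples, which pairs nothing across groups.

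In the deposited table each probe set has a log2 value per array. The values were made with RMA, per the submitters' processing notes. RMA corrects the background of the probes, normalizes between arrays and summarises the probes of a probe set on the log2 scale. The software, its version and the genome build are not given in the sources used here. The values fit that description, running from 0.07 at the lowest to 12.11 at the highest over the arrays. Array medians over all probe sets still differed between the operations, at 2.05 ± 0.02 for sham and 2.17 ± 0.02 for PHx (SD, n = 8 arrays each). A method that forces equal distributions on the tested values can hide a change shared by most genes, and one that does not can leave a shift between arrays, so other scalings were tried. Low values lie near the background, where fold changes are understated. For arrays, the number of arrays limits the precision.

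The table has 72688 probe sets. Gene symbols came from the platform annotation paired with the probe sets, in which 30604 have 1 symbol, 2146 have several and 39938 are not listed and so are unnamed here. Symbols were updated through Entrez identifiers to a RefSeq gene table, which changed 827 of them. A gene with several probe sets (355 genes) was represented by the one with the highest mean over the 16 arrays, which left 30142 genes, 19046 of them protein-coding. No gene was named from a probe set with several symbols. For that reason some genes fixed for naming, Ccnd1 among them, are not reported here. Genes with near-identical copies, such as those of the Cyp4a, Hsd3b, Saa and vomeronasal families, share probe sequence, and their values are uncertain in that respect.

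Genes were tested with limma 3.58.1 in R 4.3.3 (tables read with data.table version 1.17.8) on the values as deposited. A model with 1 mean per group was fitted to all 16 arrays by lmFit, which leaves 12 residual degrees of freedom, and eBayes moderated the variances with its defaults. Adjusted p is the Benjamini-Hochberg value over the 30142 genes, and a gene passed at adjusted p below 0.05. The 5 comparisons were PHx against sham in each genotype, PparaΔHep against fl/fl after each operation, and the difference between the genotypes' PHx changes. Each log2 fold change is given with its standard error from that model, which shares 1 spread per gene over the 4 groups. Where the groups differ in spread, that error is too wide for the tighter groups and too narrow for the others. Two-sided exact permutation tests of a list's mean per array, and of the difference of its PHx changes, were added after the results were seen. The latter exchanges genotype within each operation. It thus assumes no genotype effect after either operation, which is more than equal PHx changes.

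In all, 36 lists were fixed, 24 of pathways and 12 of cell type markers. The pathway lists were fatty acid oxidation, other classical PPARα targets, lipid droplet and fat uptake, fatty acid and triglyceride synthesis, cholesterol synthesis, bile acid synthesis and transport, immediate early and priming, G1/S and DNA replication, G2/M and mitosis, p53 targets and cell cycle inhibitors, IL-6 and STAT3 signalling, acute phase, growth factor and AKT signalling, ribosome biogenesis, unfolded protein response, gluconeogenesis with amino acid and urea metabolism, glycolysis and glucose use, xenobiotic metabolism, NRF2 targets, autophagy and lysosome, oxidative phosphorylation, circadian clock, and male-biased and female-biased liver genes. The marker lists were hepatocyte, Kupffer cell and macrophage, monocyte, neutrophil, T and NK cell, B cell, liver sinusoidal endothelial cell, stellate cell and fibroblast, cholangiocyte, erythroid and blood, pancreas, and adipocyte. Some genes stand in 2 lists, such as Plin2 in both the droplet list and the list of other targets. Each list was tested with limma's camera, which compares its genes with all other genes. The correlation between genes was preset at 0.01, and adjusted p is over the 36 lists of a comparison. Camera with an estimated correlation and limma's fry were alternatives. Counts of members that passed are over all genes tested, with the count adjusted over the list alone beside them.

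The lists, the main model, the threshold, the alternatives and the rule for naming genes were chosen before the data were examined, except where stated. The rule takes, for each comparison, the 8 largest rises and 8 largest falls among genes that passed and whose groups do not overlap, leaving out predicted and small RNA genes, up to 4 members of each list by adjusted p, and a fixed set of genes. Most of the largest rises after PHx were genes of chromosome Y and of repeated families, so the 12 largest rises of protein-coding genes outside them were added after the values were seen.

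Alternatives covered the variance prior, cyclic loess, subtraction of each array's median, leaving out the dimmer 50% of genes, the mean of a gene's probe sets, all probe sets as tests, array weights, the 8 compared arrays alone, the first 3 digits of the number in the sample titles as a block, a threshold of 0.01, a minimum fold of 1.5, and leaving out each array in turn. Protein-coding genes outside chromosome Y and repeated families were added as an alternative after the data were seen. The numbers in the titles are unexplained in the labels, and the correlation of arrays that share their first 3 digits was -0.01. Digits 104 and 107 stood on PHx arrays only and 105 on sham arrays only, while 106 held both operations. The block was fixed in the genotype comparisons and random in the others, where a correlation of -0.01 gives it almost no effect. It is therefore no check on a batch that follows the operation.

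The test was checked on simulated arrays of 30142 genes, in which 67 genes were changed 1.5-fold, 67 2-fold and 66 4-fold. The changed genes were drawn at random. Noise was independent between genes, equal in spread over the groups and without shifts between arrays, unlike the real arrays. The shares therefore check the procedure and do not give the recovery or false calls of the real data. For PHx in fl/fl livers the test recovered 80.6% of genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold, with 10 false calls among 196. For PHx in PparaΔHep livers the shares were 76.1%, 95.5% and 100%, with 12 false calls among 193. For genotype after sham they were 68.7%, 95.5% and 98.5%, with 8 false calls among 183. For genotype after PHx they were 85.1%, 95.5% and 100%, with 4 false calls among 191. For the difference of the PHx changes they were 56.7%, 80.6% and 98.5%, with 11 false calls among 168. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.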

Results

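Liver RNA was measured on 16 arrays, 4 in each group formed by operation and genotype. Partial hepatectomy (PHx) removes part of the liver and starts regrowth of the rest, while a sham operation leaves the liver whole. PPARα, encoded by Ppara, is a nuclear receptor that senses fatty acids and switches on genes of fat oxidation. The fl/fl mice served as wild type, and in PparaΔHep mice the gene was disrupted in hepatocytes. The livers were taken at 12 h, a time chosen per the labels because fat builds up in the regrowing liver then. The comparisons ask how the transcriptome responds to PHx and what that response owes to hepatocyte PPARα. Within groups, the median SD of a gene over the 4 arrays was 0.09 for both sham groups and 0.11 for both PHx groups on the log2 scale. Correlations across genes ranged from 0.986 to 0.997 between arrays of a group and from 0.955 to 0.977 between arrays of different operations. No pair of arrays held identical values. The first principal component carried 70.8% of the variance and parted all 8 PHx arrays from all 8 sham arrays.

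The disrupted gene and a classical target were examined first. Ppara stood at 6.81 ± 0.26 in sham fl/fl, 6.30 ± 0.18 in sham PparaΔHep, 6.49 ± 0.74 in PHx fl/fl and 5.32 ± 0.67 in PHx PparaΔHep livers (log2 level, SD, n = 4). The genotype differences of -0.50 ± 0.33 after sham and -1.17 ± 0.33 after PHx (SE) did not pass (limma adjusted p = 0.681 and 0.326). That SE rests on 1 spread shared by the 4 groups, while the SDs were larger after PHx than after sham. The SE is thus likely too wide after sham and too narrow after PHx. The probe set may cover exons outside the deleted part, so it does not settle the labels. Cyp4a14, a fatty acid hydroxylase and PPARα target, stood at 7.48 ± 1.51 in sham fl/fl, 3.29 ± 1.09 in sham PparaΔHep, 8.77 ± 1.92 in PHx fl/fl and 4.32 ± 2.23 in PHx PparaΔHep livers. Its genotype differences of -4.20 ± 1.11 and -4.45 ± 1.11 did not pass either (adjusted p = 0.383 and 0.214).

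In fl/fl livers, PHx raised some genes of the lipid droplet, although their list was not called, and lowered the lists of cholesterol synthesis, unfolded protein response and male-biased liver genes by camera at the preset correlation, though not with an estimated one (adjusted p = 0.655). Cidec, which fuses lipid droplets, rose by 3.46 ± 0.38 on the log2 scale (SE; adjusted p = 8.12e-06), and the droplet coat genes Plin4 and Plin5 rose by 1.94 ± 0.35 and 0.87 ± 0.15. The level of their relative Plin2 rose from 8.47 ± 0.14 to 9.98 ± 0.13 (SD, n = 4; limma adjusted p = 9.02e-07). Mfsd2a, a transporter of lysophospholipids, rose by 3.65 ± 1.12. Pdk4, a brake on glucose oxidation, rose by 2.99 ± 0.59, the thioesterase Acot2 by 2.20 ± 0.39 and the carnitine importer Slc22a5 by 1.49 ± 0.20. Tnfrsf12a, the receptor of the cytokine TWEAK, rose by 2.65 ± 0.36 and the leptin receptor gene Lepr by 2.25 ± 0.52. The haem-degrading enzyme gene Hmox1 rose by 1.37 ± 0.32, and Got1 and the urea cycle gene Arg1 by 1.97 ± 0.41 and 0.77 ± 0.11. The largest falls were of Derl3, which helps remove misfolded proteins from the endoplasmic reticulum, at -4.08 ± 0.44, and of Hsd3b5, a steroid dehydrogenase of male liver, at -4.02 ± 0.37. Keg1 fell by 3.00 ± 0.44. All values rest on 4 arrays per group.

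Of the 36 lists, 8 were called in fl/fl livers. Cholesterol synthesis fell most widely, with 17 of 18 measured members lower (17 adjusted over the list alone), among them Fdps at -1.65 ± 0.21, Mvk at -1.42 ± 0.18 and Insig1, the sterol sensor's partner, at -1.48 ± 0.19 (camera adjusted p = 7.29e-07). Male-biased liver genes fell in 10 of 16 members (10 adjusted over the list alone), including Elovl3, a fatty acid elongase, at -2.28 ± 0.39 (adjusted p = 0.0131). Genes of the unfolded protein response fell in 9 of 21 (9 adjusted over the list alone), with the chaperone gene Dnajc3 at -0.87 ± 0.10 and Edem1, of endoplasmic reticulum degradation, at -0.91 ± 0.12 (adjusted p = 0.0353). Autophagy and lysosome genes fell in 9 of 21 (10 adjusted over the list alone), with Gabarapl1 at -1.29 ± 0.15 and Lamp1 at -0.45 ± 0.07 (adjusted p = 0.0131). Oxidative phosphorylation genes fell in 8 of 23 (10 adjusted over the list alone; adjusted p = 0.0229). Hepatocyte markers fell in 5 of 14, with the antithrombin gene Serpinc1 at -0.53 ± 0.07 and the prothrombin gene F2 at -0.47 ± 0.06 (adjusted p = 0.0353; 6 lower and 1 higher adjusted over the list alone). Immediate early genes rose in 2 of 22 (0 adjusted over the list alone), the transcription factor genes Jun at 0.96 ± 0.27 and Klf6 at 1.62 ± 0.50 (adjusted p = 0.0229). The list's mean level was 5.48 and 5.22 on PHx fl/fl arrays 2 and 3, but 4.39 and 4.31 on arrays 1 and 4, inside the range of sham fl/fl arrays (4.30 to 4.53). Ribosome biogenesis genes rose in 3 of 29 and fell in 1 (3 and 1 adjusted over the list alone), with the rRNA methyltransferase gene Nop2 at 0.56 ± 0.16 (adjusted p = 0.0349). In exact two-sided permutations of the list means p was 0.229 for immediate early, 0.114 for ribosome biogenesis, 0.114 for oxidative phosphorylation and 0.0286, the smallest possible, for the other 5 lists (0.0735 after adjustment over 36 lists). None of the 8 calls held with an estimated correlation (adjusted p = 0.655 with an estimated correlation for the 6 falling lists, 0.687 for immediate early and 0.766 for ribosome biogenesis).

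Fatty acid oxidation as a list did not move one way in fl/fl livers (adjusted p = 0.966). Its mean level on PHx fl/fl arrays 1 and 4 (7.66 and 7.63) lay above all sham fl/fl arrays (7.27 to 7.55), and on arrays 2 and 3 (7.05 and 7.02) below all of them. Eci2 and Pex11a, of peroxisomes, rose by 0.75 ± 0.18 and 0.88 ± 0.19 while Acads and Crot, of short-chain and peroxisomal oxidation, fell by 0.81 ± 0.11 and 0.98 ± 0.26. In that list 3 of 29 members rose and 4 fell (3 and 3 adjusted over the list alone). Its median was -0.10 and its mean -0.04 while the direction camera gave was up, and the median became 0.09 after cyclic loess. Other classical PPARα targets rose in 9 and fell in 5 of 31 members (10 and 5 adjusted over the list alone; adjusted p = 0.108). Lipid droplet and fat uptake genes rose in 7 and fell in 1 of 25 (7 and 1 adjusted over the list alone, camera adjusted p = 0.185), with a median of -0.07 but a mean of 0.37 and an upward direction in camera. In the exact two-sided permutation of list means the droplet list had p = 0.0286 (0.0735 adjusted over 36 lists). Cell cycle lists were not called, with 2 higher and 6 lower of 36 G1/S genes (1 and 6 adjusted over the list alone; adjusted p = 0.564) and 1 higher and 2 lower of 25 G2/M genes (0 and 0 adjusted over the list alone; adjusted p = 0.774). The mean level of the G2/M genes was 1.93 in sham and 1.89 in PHx fl/fl livers, near the negative control medians of 1.90 and 2.02. These arrays could thus show little change of them. The values of the proliferation marker Mki67, Myc and Cdkn1a were -0.10 ± 0.13 (adjusted p = 0.592), 0.41 ± 0.20 (0.141) and 0.79 ± 0.88 (0.524). Those of Phlpp2, Pparg and the hormone gene Fgf21 were 0.02 ± 0.08 (0.879), -0.31 ± 0.19 (0.229) and 0.47 ± 0.28 (0.216).

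In total 9868 of 30142 genes passed in fl/fl livers, 3597 higher and 6271 lower (36.5% higher), and 2336 of them changed at least 1.5-fold, 1173 up and 1163 down. In 32.0% of all genes the 4 arrays of one group lay above the 4 of the other, against 2.86% by chance. The split by direction depended on the scale, with 56.7% of 7512 genes higher after cyclic loess and 28.0% of 10894 after subtraction of array medians. The hepatocyte markers' median of -0.13 turned to 0.04 after cyclic loess. The largest rises by the naming rule included genes of chromosome Y and of repeated families, such as Orly at 4.63 ± 0.12, Speer8-ps1 at 3.98 ± 0.09 and the vomeronasal receptor gene Vmn1r114 at 3.32 ± 0.12. The median over all chromosome Y probe sets was 5.19 ± 0.16 on PHx arrays and 1.81 ± 0.06 on sham arrays (SD, n = 8 each). Antigenomic background probe sets stood lower on PHx arrays, at 1.01 ± 0.04 against 1.24 ± 0.03. So did positive control probe sets, at 5.59 ± 0.12 against 5.95 ± 0.09, and ERCC spike-in probe sets, at 1.53 ± 0.04 against 1.73 ± 0.06, with no overlap of the arrays, while negative controls stood at 2.02 ± 0.07 against 1.94 ± 0.06. List medians called lower in fl/fl livers, such as -0.13 for hepatocyte markers, -0.16 for oxidative phosphorylation and -0.24 for autophagy, are of similar size to these shifts. After cyclic loess these medians were 0.04, -0.00 and -0.07, and with array medians subtracted -0.16, -0.19 and -0.27. Among protein-coding genes outside those families, an alternative chosen after seeing the data, 5817 passed and 18.4% of them were higher.

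Some calls in fl/fl livers rested on single arrays. Mfsd2a lost its call without sham fl/fl array 2 or 3 or PHx fl/fl array 2 or 3 (adjusted p from 0.0509 to 0.0687), and Klf6 without sham fl/fl array 3 or PHx fl/fl array 2 or 3 (0.0511 to 0.0719). Among the lists, immediate early lost its call without PHx fl/fl array 2 or 3, ribosome biogenesis without PHx fl/fl array 1 or 3 or sham fl/fl array 3 (adjusted p up to 0.164 without PHx fl/fl array 3), and unfolded protein response without PHx fl/fl array 2 or 4 or sham fl/fl array 1, 2 or 4 (up to 0.122 without PHx fl/fl array 4). Oxidative phosphorylation lost its call without PHx fl/fl array 1 or sham fl/fl array 4 (up to 0.0574 without the latter), and hepatocyte markers lost theirs without sham fl/fl array 1 or 4 or PHx fl/fl array 1 or 3 (up to 0.0696 without sham fl/fl array 4).

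In PparaΔHep livers, PHx lowered the lists of fat oxidation, fat synthesis, cholesterol and bile acid synthesis and respiration by camera at the preset correlation. With an estimated correlation none of the 12 lists called there passed (adjusted p from 0.206 to 0.740). After cyclic loess the medians shrank, from -0.39 to -0.19 for fatty acid oxidation, -0.29 to -0.09 for oxidative phosphorylation and -0.46 to -0.28 for bile acid synthesis. With array medians subtracted they were larger falls instead, at -0.52, -0.42 and -0.59. Positive control probe sets stood at 5.54 ± 0.16 on PHx and 6.01 ± 0.05 on sham PparaΔHep arrays (SD, n = 4). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 5.29 ± 1.23 (adjusted p = 0.00437). The size of that fall is uncertain, since its PHx level was 6.39 on array 1 and 1.79 to 2.54 on the others, near the negative controls (2.02). Hsd3b7, of the same pathway, fell by 1.61 ± 0.25. Derl3 and Hsd3b5 fell by 3.59 ± 0.44 and 3.68 ± 0.37, and Igfals, whose product stabilises IGF-1 in blood, fell by 3.04 ± 0.39. The glycogen-targeting subunit gene Ppp1r3c fell by 2.73 ± 0.41 and G6pc, the last enzyme of gluconeogenesis, by 2.60 ± 0.69. Sult1e1, an oestrogen sulfotransferase, rose by 3.54 ± 0.92 and Tnfrsf12a by 2.81 ± 0.36. The thyroxine carrier gene Serpina7 rose by 2.61 ± 0.52, Klf6 by 2.01 ± 0.50, Krt8 by 1.99 ± 0.33 and the xanthine oxidase gene Xdh by 1.91 ± 0.09. The droplet coat gene Plin2 rose by 0.94 ± 0.14, and Jun and Hmox1 by 0.98 ± 0.27 and 1.39 ± 0.32.

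In these livers 12 lists were called. Fatty acid oxidation fell in 13 of 29 members and rose in 0 (14 and 0 adjusted over the list alone), with Crot, Crat, Acads and Hadh at -1.39 ± 0.26, -1.27 ± 0.21, -0.93 ± 0.11 and -0.92 ± 0.20 (adjusted p = 3.82e-04; adjusted p = 0.607 with an estimated correlation). Fatty acid and triglyceride synthesis fell in 14 of 20 (14 adjusted over the list alone), with Acss2, which makes acetyl-CoA from acetate, at -1.31 ± 0.16 (adjusted p = 1.09e-04; adjusted p = 0.206 with an estimated correlation). Cholesterol synthesis fell in 18 of 18 (18 adjusted over the list alone), with Fdps, Mvk and Insig1 at -1.54 ± 0.21, -1.51 ± 0.18 and -1.40 ± 0.19 (adjusted p = 1.86e-10; adjusted p = 0.237 with an estimated correlation). Bile acid synthesis and transport fell in 10 of 22 and rose in 3 (10 and 3 adjusted over the list alone), the uptake transporter gene Slco1a4 by 1.59 ± 0.40 (adjusted p = 0.0369; adjusted p = 0.451 with an estimated correlation). Oxidative phosphorylation fell in 15 of 23 (18 adjusted over the list alone), with Uqcrc1, a core subunit of complex III, at -0.63 ± 0.08 (adjusted p = 8.17e-06; adjusted p = 0.485 with an estimated correlation). Autophagy and lysosome genes fell in 10 of 21 (12 adjusted over the list alone; Gabarapl1 at -1.65 ± 0.15), unfolded protein response genes in 10 of 21 (10 adjusted over the list alone; Dnajc3 at -0.72 ± 0.10) and male-biased genes in 8 of 16 (9 adjusted over the list alone; Elovl3 at -2.52 ± 0.39). Their adjusted p were 3.30e-04, 0.0322 and 3.30e-04, and with an estimated correlation the adjusted p were 0.206, 0.582 and 0.237.

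Among the markers of non-parenchymal cells, the lists of Kupffer cells and of sinusoidal endothelial cells were called in PparaΔHep livers, and the others were not. Kupffer cell and macrophage markers fell in 8 of 12 (8 adjusted over the list alone), with the growth factor receptor gene Csf1r at -0.88 ± 0.12 and Adgre1, the F4/80 antigen, at -1.03 ± 0.19 (adjusted p = 0.00832; adjusted p = 0.564 with an estimated correlation). Liver sinusoidal endothelial markers fell in 7 of 11 and rose in 1 (8 and 1 adjusted over the list alone), with the VEGF receptor gene Kdr at -1.31 ± 0.20, Clec4g at -1.16 ± 0.17 and Dnase1l3 at -0.92 ± 0.11 (adjusted p = 0.00488; adjusted p = 0.237 with an estimated correlation). In fl/fl livers the same lists fell in 4 of 12 and in 6 of 11, with 1 endothelial member higher (4, and 6 and 1, adjusted over the list alone), and were not called (adjusted p = 0.185 and 0.153). The endothelial mean fell there too, from 5.29 ± 0.05 to 4.99 ± 0.05 (SD, n = 4, exact permutation p = 0.0286, 0.0735 adjusted). A call in 1 genotype alone does not show a difference. Tested directly, the difference had camera adjusted p = 0.0315 and 0.0339, but permutation p = 0.457 and 0.190 for the Kupffer and endothelial list means. Hepatocyte markers fell in 4 of 14 (4 adjusted over the list alone; adjusted p = 0.0322; adjusted p = 0.451 with an estimated correlation), and their median of -0.07 turned to 0.06 after cyclic loess. Immediate early genes rose in 2 of 22 (2 adjusted over the list alone; adjusted p = 0.0433; adjusted p = 0.740 with an estimated correlation), with list means of 4.37, 4.58, 5.13 and 5.39 on PHx PparaΔHep arrays 1 to 4 and 4.24 to 4.54 on sham arrays. In exact two-sided permutations of the list means p was 0.114 for immediate early, 0.0571 for unfolded protein response and 0.0286 for the other 10 lists called (0.0541 after adjustment over 36 lists). The cell cycle lists were again not called, with 3 higher and 6 lower of 36 G1/S genes (2 and 5 adjusted over the list alone; adjusted p = 0.322) and 0 higher and 1 lower of 25 G2/M genes (0 and 0 adjusted over the list alone; adjusted p = 0.475). The G2/M genes again lay near the negative controls, with means of 1.92 in sham and 1.89 in PHx PparaΔHep livers against control medians of 1.98 and 2.02. Within the G1/S list Ccne1, which encodes cyclin E1, rose by 0.70 ± 0.14 and the replication factor gene Mcm10 fell by 1.03 ± 0.11.

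In total 9734 genes passed in PparaΔHep livers, 4461 higher and 5273 lower (45.8% higher), and 2689 of them changed at least 1.5-fold, 1235 up and 1454 down. The share higher was 53.7% of 8019 genes after cyclic loess and 16.5% of 13748 after subtraction of array medians, which moved the median change of all genes from 0.01 to -0.12. Among protein-coding genes outside chromosome Y and repeated families it was 26.7% of 5959. Ppara itself changed by -0.98 ± 0.33 (adjusted p = 0.0350), a call lost without any of 6 arrays, sham PparaΔHep arrays 1, 2 and 3 and PHx PparaΔHep arrays 2, 3 and 4 (adjusted p up to 0.113), and after cyclic loess (0.0948). Without 1 array, calls were lost in PparaΔHep livers for bile acid synthesis (PHx array 2 or 3 or sham array 3, adjusted p up to 0.0740 without PHx array 2), immediate early genes (sham array 1 or 2 or PHx array 3 or 4, up to 0.207 without PHx array 4), unfolded protein response (0.126 without PHx array 2) and hepatocyte markers (PHx array 2 or 3, up to 0.0740 without array 2).

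Across genes, the PHx changes of the genotypes ran together, with a Pearson correlation of 0.932 and a Spearman correlation of 0.779 over 30142 genes, which are not independent replicates. The comparisons share no array. Among protein-coding genes outside chromosome Y and repeated families the Pearson correlation was 0.870. Of the genes that passed, 6277 passed in both genotypes, 2623 higher in both, 3639 lower in both and 15 in opposite directions. Independent lists of these sizes would share 532 higher and 1100 lower genes. A technical difference that follows the operation would move both genotypes alike. The correlation and the overlap therefore cannot tell a response of the liver from such a difference. Xdh, Tnfrsf12a and the clock gene Per2, which rose by 1.93 ± 0.09, 2.65 ± 0.36 and 1.20 ± 0.18 in fl/fl livers, rose by 1.91 ± 0.09, 2.81 ± 0.36 and 1.17 ± 0.18 in PparaΔHep livers.

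**Figure D1:**
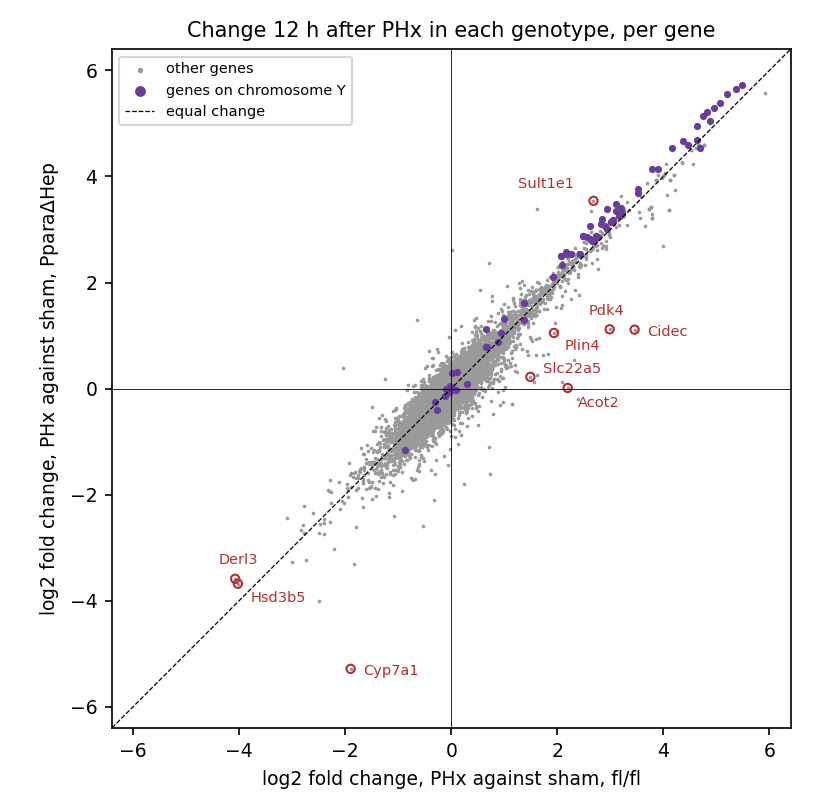
Each point is 1 of 30142 genes, with its log2 fold change of PHx against sham in fl/fl livers on the x axis and in PparaΔHep livers on the y axis (4 arrays per group). The points follow the dashed line of equal change (Pearson correlation 0.932), genes of chromosome Y lie mostly at the upper right, and Cidec lies at 3.46 on the x axis and 1.11 on the y axis.

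After sham, Acadvl, the enzyme that starts mitochondrial oxidation of very-long-chain fatty acids, was lower in PparaΔHep livers by -0.86 ± 0.12 (adjusted p = 0.0166). Fatty acid oxidation as a list was lower, with a median of -0.42 and 1 of 29 members past the threshold over all genes but 17 lower adjusted over the list alone. Among the members that did not pass, Decr2, a peroxisomal reductase for unsaturated fats, differed by -1.18 ± 0.19 (adjusted p = 0.109) and Ech1 by -0.91 ± 0.15 (0.112). The list's mean level was 6.93 ± 0.10 in PparaΔHep and 7.37 ± 0.12 in fl/fl livers (SD, n = 4), all 4 arrays lower (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 arrays can give; 0.343 after adjustment over 36 lists). By camera the adjusted p was 6.42e-15, and adjusted p = 0.403 with an estimated correlation, while fry gave 0.149. Other classical targets were also lower (median -0.12, 0 of 31 past the threshold, 8 lower and 2 higher adjusted over the list alone; adjusted p = 0.0202; adjusted p = 0.603 with an estimated correlation). In that list Vnn1, a pantetheinase, differed by -2.60 ± 0.47 (adjusted p = 0.168) and Acot1 by 1.12 ± 0.26 (0.337). With array medians subtracted the median of the other targets was -0.05.

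The other genes that passed after sham were Serinc2 at -1.25 ± 0.13 (adjusted p = 0.00271), Qpct at -1.01 ± 0.13 (0.0166) and the non-coding RNA gene Snhg11 at 0.48 ± 0.06 (0.0166), which makes 4 of 30142. At an unadjusted p below 0.05 there were 2792, and in 6.80% of genes the groups did not overlap, against 2.86% by chance. Subtraction of array medians left 2 genes, 1 higher and 1 lower. The count rose to 24 with array weights and to 38 in a fit of the 8 sham arrays alone. Acadvl lost its call without any of 7 of the 8 sham arrays, the exception being PparaΔHep array 3 (adjusted p up to 0.111 without PparaΔHep array 4). Qpct lost its call without sham PparaΔHep array 1, 2 or 4 or sham fl/fl array 3, and Snhg11 without sham PparaΔHep array 1, 2 or 3 or sham fl/fl array 1, 3 or 4 (each up to 0.105 without PparaΔHep array 1), while Serinc2 kept its call without each of the 16 arrays in turn. The list of other targets lost its call without sham PparaΔHep array 1 or 4 or sham fl/fl array 4 (0.0631, 0.077 and 0.12). With the first 3 digits of the title numbers as a block, 4 genes passed, 2 higher and 2 lower, and 3 of them were among the 4 of the main fit. With that block the camera adjusted p were 7.79e-15 for oxidation and 0.0304 for other targets. Within the blocks, of 1 to 3 arrays per genotype, the oxidation mean differed by -0.38 in block 105 and -0.56 in block 106 and that of other targets by -0.30 and -0.59.

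A further 7 lists were called higher in sham PparaΔHep livers, by medians of 0.05 to 0.14, with 0 members past the threshold over all genes. These medians are small, near in size to the gap between the array medians of tested genes. That gap runs the other way, at 2.65 ± 0.03 in PparaΔHep and 2.71 ± 0.04 in fl/fl livers (SD, n = 4). The list medians were 0.11 to 0.20 with array medians subtracted. The 7 lists were unfolded protein response (adjusted p = 0.00773), fatty acid and triglyceride synthesis (0.00824), autophagy and lysosome (0.00824), circadian clock (0.0147), cholesterol synthesis (0.0309), male-biased genes (0.0309) and Kupffer cell and macrophage (0.0309). With an estimated correlation their adjusted p ranged from 0.219 to 0.811. In exact two-sided permutations of the list means p was 0.0286 for unfolded protein response (0.343 adjusted over 36 lists). For the rest it ran from 0.0571 for autophagy to 0.514 for fatty acid synthesis (0.343 to 0.831 adjusted). All but the unfolded protein response lost their calls without at least 1 sham array. These were PparaΔHep array 4 for the clock (adjusted p = 0.142), PparaΔHep array 3 for autophagy (0.0535), PparaΔHep array 4 or fl/fl array 3 for fatty acid synthesis (up to 0.109 without the former), and PparaΔHep array 3 or 4 or fl/fl array 3 for cholesterol (up to 0.364 without PparaΔHep array 4). For male-biased genes they were PparaΔHep array 3 or 4 or fl/fl array 1 or 4 (up to 0.152 without PparaΔHep array 3), and for Kupffer cells PparaΔHep array 1 or 3 or fl/fl array 1 or 4 (up to 0.439 without fl/fl array 1). Adjusted over the list alone, 1 member of the unfolded protein response list and 0 of the others passed.

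After PHx, PparaΔHep livers had lower levels of genes that carry fatty acids into mitochondria and oxidise them, and of genes of the lipid droplet. Of 35 splits of the 8 PHx arrays into 4 and 4, 3 gave at least the real count of genes. Chance is therefore not excluded for that count. Slc25a20 and Cpt2, the carrier and the transferase that bring acylcarnitines into the mitochondrion, fell by 1.54 ± 0.21 and 1.29 ± 0.16 relative to fl/fl (adjusted p = 0.00623 and 0.00280). Acadvl, Ech1 and Eci2, of mitochondrial and peroxisomal oxidation, were lower by -1.12 ± 0.12, -1.13 ± 0.15 and -1.41 ± 0.18 (adjusted p = 0.00114, 0.00506 and 0.00381). Plin5, which holds droplets to mitochondria, was lower by -1.37 ± 0.15 and Cidec by -2.40 ± 0.38. The carnitine importer gene Slc22a5 was lower by -1.27 ± 0.20, the cholesteryl ester hydrolase gene Nceh1 by -1.37 ± 0.16 and the transcription factor gene Creb3l3 by -0.73 ± 0.07. Hsd17b7, of cholesterol synthesis, was lower by -0.99 ± 0.16 and Rarres1 by -1.69 ± 0.27. Cyp4a31, a target with near-identical copies, differed by -3.24 ± 0.61 (adjusted p = 0.0607), and Plin2 by -0.62 ± 0.14 (0.136).

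Fatty acid oxidation was lower in 11 of 29 members, 26 adjusted over the list alone, with a median of -0.81 (camera adjusted p = 1.83e-54, and adjusted p = 0.0104 with an estimated correlation). Other classical targets were lower in 2 of 31, 17 adjusted over the list alone, with a median of -0.64 (adjusted p = 4.88e-22, and adjusted p = 0.0063 with an estimated correlation). Lipid droplet and fat uptake genes were lower in 2 of 25, with 8 lower and 1 higher adjusted over the list alone and a median of -0.23 (adjusted p = 9.45e-08, and adjusted p = 0.0104 with an estimated correlation). The list means were 6.52 ± 0.13 against 7.34 ± 0.35, 4.97 ± 0.40 against 5.87 ± 0.24 and 4.91 ± 0.13 against 5.30 ± 0.09 in PparaΔHep and fl/fl livers (SD, n = 4). All 4 arrays were lower in each (exact two-sided permutation p = 0.0286 each, 0.257 after adjustment over 36 lists). With the title-number block the camera adjusted p were 1.25e-53, 1.37e-20 and 1.06e-06. Within the blocks, of 1 or 2 arrays per genotype, the means differed by -1.16, -1.48 and -0.62 in block 104 and by -0.78, -0.53 and -0.20 in block 107.

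**Figure D2:**
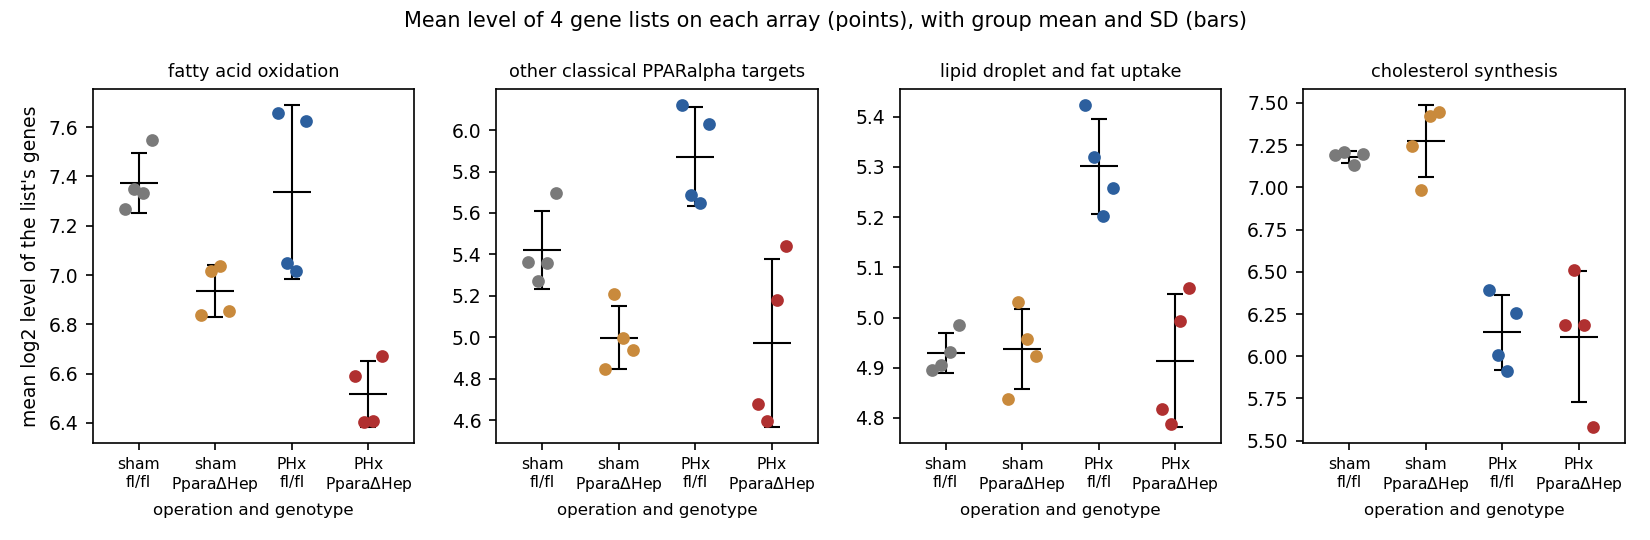
Mean log2 level of the measured genes of 4 lists on each array (points), by operation and genotype, with the group mean and SD (bars, n = 4). Fatty acid oxidation is lower in PparaΔHep than in fl/fl livers after sham (6.93 and 7.37) and after PHx (6.52 and 7.34), lipid droplet genes differ after PHx only in these means (4.91 and 5.30, against 4.94 and 4.93 after sham), and cholesterol synthesis is lower after PHx in both genotypes.

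A further 8 lists were called after PHx, with 0 members past the threshold over all genes in each. Xenobiotic metabolism was higher in PparaΔHep livers (median 0.29, 7 of 21 higher adjusted over the list alone, adjusted p = 6.72e-07; adjusted p = 0.104 with an estimated correlation), where Cyp2a4 differed by 1.17 ± 0.25 (adjusted p = 0.113). Unfolded protein response (median 0.20, adjusted p = 8.62e-04) and NRF2 targets (0.17, 0.0225) were higher too, with 0 members adjusted over the list alone and adjusted p = 0.344 and 0.603 with an estimated correlation. Oxidative phosphorylation (median -0.12, adjusted p = 1.62e-08), gluconeogenesis with amino acid and urea metabolism (-0.26, 2.15e-05), sinusoidal endothelial markers (-0.17, 0.00362), fatty acid and triglyceride synthesis (-0.03, 0.0175) and glycolysis (-0.08, 0.0414) were lower. Of these, 2 members of fatty acid synthesis and 1 of glycolysis passed adjusted over the list alone, and the adjusted p with an estimated correlation were 0.300, 0.300, 0.218, 0.300 and 0.295. In exact two-sided permutations of the list means p was 0.0286 for xenobiotic metabolism, as for oxidation, other targets and droplet genes (0.257 adjusted over 36 lists). For the rest of the 8 lists it ran from 0.0571 for fatty acid synthesis to 0.286 for NRF2 targets (0.343 to 0.514 adjusted). Without 1 PHx array, calls were lost for unfolded protein response (adjusted p = 0.263 without PparaΔHep array 1), endothelial markers (0.0818 without PparaΔHep array 4), fatty acid synthesis (PparaΔHep array 2 or fl/fl array 4, up to 0.135 without the former), glycolysis (PparaΔHep array 2 or 3 or fl/fl array 2 or 4, up to 0.215 without PparaΔHep array 2) and NRF2 targets (PparaΔHep array 3 or 4 or fl/fl array 1 or 4, up to 0.479 without PparaΔHep array 3).

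Over all genes, 43 passed after PHx, all lower in PparaΔHep livers, 35 of them at least 1.5-fold, and 2253 had an unadjusted p below 0.05. Of the 43 genes, 40 had the same sign after sham, and Acadvl was the 1 gene past the threshold after both operations. The count fell to 0 in a fit of the 8 PHx arrays alone and to 26, 21 of them among the 43, with the title-number block. In a fit of the 8 sham arrays alone the count after sham rose from 4 to 38. The order of the 2 counts thus depends on which arrays share the estimate of spread. The counts alone do not show that the genotype effect grew after PHx. The count after PHx was 28 without sham PparaΔHep array 1, sham fl/fl array 1 or sham fl/fl array 3, and 14 without PHx PparaΔHep array 2. It was 17 and 21 without PHx fl/fl array 1 and 4, and 127, including all 43, without PHx fl/fl array 3. Among the named genes, calls were lost without 1 array for Cidec (up to 0.0951), Slc22a5 (up to 0.0955), Rarres1 (up to 0.0918) and Hsd17b7 (up to 0.0894), each highest without PHx fl/fl array 1. Other arrays that ended these calls were PHx PparaΔHep array 2 (all 4 genes), PHx PparaΔHep array 1 (Slc22a5 and Hsd17b7), PHx PparaΔHep array 4 (Hsd17b7), PHx fl/fl array 2 (Cidec and Rarres1) and PHx fl/fl array 4 (Slc22a5, Rarres1 and Hsd17b7).

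**Figure D3:**
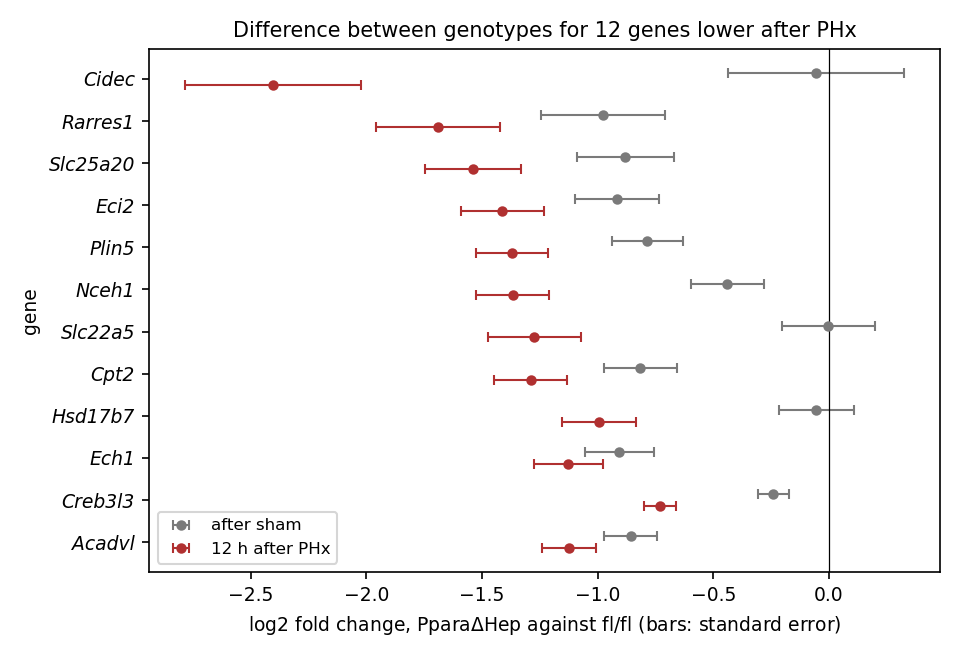
Log2 fold change of PparaΔHep against fl/fl livers for 12 genes lower after PHx (x axis, genes on the y axis; bars show the standard error, 4 arrays per group). After PHx the values run from -2.40 for Cidec to -0.73 for Creb3l3, and after sham those of Cidec, Slc22a5 and Hsd17b7 lie at -0.06, -0.00 and -0.05. Others, such as Acadvl and Ech1, were already lower after sham. The genes were picked among those that passed after PHx, which favours larger differences there. In limma's direct test no gene's PHx change differed between genotypes past the threshold.

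The difference between the genotypes' PHx changes was tested directly. It passed in limma for 0 of 30142 genes, with 3400 at an unadjusted p below 0.05 and a smallest adjusted p of 0.286. Creb3l3, which rose by 0.39 ± 0.07 after PHx in fl/fl livers and changed by -0.10 ± 0.07 in PparaΔHep livers, differed by -0.49 ± 0.10 (adjusted p = 0.286). Cidec changed by 3.46 ± 0.38 and 1.11 ± 0.38, a difference of -2.35 ± 0.54 (0.315). The differences were -1.80 ± 0.36 for Acot1 (0.286), -1.27 ± 0.28 for Slc22a5 (0.301), -2.19 ± 0.55 for Acot2 (0.327) and -0.57 ± 0.19 for Plin2 (0.352). The count was 1, 2 and 1 without PHx PparaΔHep array 1, PHx fl/fl array 3 and PHx fl/fl array 4.

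As lists, 12 differed by camera. The PHx change was lower in PparaΔHep livers for fatty acid oxidation (median difference -0.38, adjusted p = 2.66e-09), other classical targets (-0.35, 5.60e-06), lipid droplet genes (-0.23, 1.65e-04), fatty acid synthesis (-0.14, 2.91e-04) and gluconeogenesis (-0.18, 6.11e-04), and higher for xenobiotic metabolism (0.26, 0.00579). Adjusted over the list alone, 2, 5, 2, 1, 0 and 0 of their members passed. These calls held without each array in turn but not with an estimated correlation (adjusted p = 0.340, 0.159, 0.159, 0.159, 0.444 and 0.340 with an estimated correlation). Oxidative phosphorylation (6.11e-04), the clock (0.0204), cholesterol synthesis (0.0315), Kupffer cells (0.0315), endothelial cells (0.0339) and pancreas (0.0367) were called as well. Adjusted over the list alone, 1 cholesterol gene and 0 of the others passed, and the adjusted p were 0.546, 0.159, 0.790, 0.615, 0.340 and 0.320 with an estimated correlation. Oxidative phosphorylation lost its call without PHx fl/fl array 4 (0.0828) and the clock without sham PparaΔHep array 4 (0.0766). The calls of cholesterol synthesis, Kupffer cells, endothelial cells and pancreas were lost without any of 6, 8, 6 and 7 arrays (up to 0.754 without PHx PparaΔHep array 4, 0.155 without sham fl/fl array 1, 0.176 without PHx PparaΔHep array 4 and 0.0760 without PHx fl/fl array 4). The cell cycle lists did not differ past the threshold (adjusted p = 0.640 for G1/S and 0.588 for G2/M, whose genes lay near the negative controls). In an exact two-sided permutation of the arrays' list means (4900 regroupings), the difference was -0.38 for fatty acid oxidation (p = 0.354, 0.788 adjusted over 36 lists; PHx fl/fl arrays 1 and 4 and arrays 2 and 3 lay on either side of the sham arrays), -0.48 for other targets (0.302, 0.788) and -0.39 for lipid droplet genes (0.0135, 0.220). The smallest exact permutation p of the 36 lists was that of pancreas markers (0.15; p = 0.00449, 0.162 adjusted), and the clock (-0.15; 0.0184, 0.220) and T and NK cells (0.10; 0.0314, 0.282) followed the droplet list. With array medians subtracted the median difference went from 0.13 to 0.03 for both pancreas and T and NK cells and from -0.23 to -0.33 for droplet genes. That subtraction shifts all lists by the same amount, so it cannot tell which list is sturdier. After cyclic loess the median differences were 0.09 for pancreas, 0.05 for T and NK cells and -0.25 for droplet genes.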

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

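The test of the animals' sex was chosen after the result was seen, while the other tests given here were planned.

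Probe sets of chromosome Y were higher on all 8 PHx arrays than on all 8 sham arrays for 62 of 75 tested genes (82.7%), with a median rise of 2.80 on the log2 scale, and for 466 of 483 chromosome Y probe sets that entered no test (96.5%), with a median rise of 3.40. Members of repeated families moved less, by medians of 0.15 for 288 vomeronasal type 1 receptor genes, 0.24 for 204 type 2 genes and 0.59 for 13 genes of the Speer family. The sex of the animals is argued against, since the mean of the single-copy genes Eif2s3y, Kdm5d and Uty differed by -0.25, away from the rise (SD between arrays 0.08), and the normalization is argued against as the whole source, since 5192 other genes at the same sham level rose by a median of 0.0238. Genomic DNA in the PHx samples stays open. The 1077 olfactory receptor genes, taken here as silent in liver, were higher by a mean of 0.21 (SD between sham arrays 0.01). That rise cannot tell genomic DNA from a lift of other dim probe sets. The 5192 genes compared had a median sham level of 1.85, against 1.15 for the olfactory receptor genes. A difference in labelling or hybridisation between the operations may contribute too and cannot be told apart from the operation, as the labels give no batch, and no biological explanation other than sex was tested.

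Other splits of the arrays bear on the gene counts. Of 35 splits of the 8 arrays into 4 and 4, only the real one, 1 split, gave as many genes for PHx in fl/fl livers (9868, highest other 2), for PHx in PparaΔHep livers (9734, highest other 0) and for genotype after sham (4, highest other 1). That share, 1 of 35, is the smallest possible, was not adjusted over the comparisons and takes the arrays as separate mice. For PHx the other splits mix the operations, which widens the spread, so a large PHx effect alone keeps their counts low. For genotype after sham, 3 of the 4 genes lost their call without 1 array, so chance is not excluded there. For genotype after PHx, 3 of 35 splits gave at least the real count of 43, so chance cannot be excluded. The highest, 2095 genes, set PHx PparaΔHep arrays 1 and 2 with PHx fl/fl arrays 1 and 4 against the rest, which points to a structure of the PHx arrays that the genotype does not follow and that partly follows the title numbers, of which 104 covers 3 of those 4 arrays. The mean of the immediate early list was 4.31 to 4.58 on those 4 arrays and 5.13 to 5.48 on the other 4 PHx arrays. With the title-number block the count was 26. For the difference of the PHx changes the real count was 0, so that 100 of 100 drawn regroupings had to give at least as many and the count says nothing about chance. The highest gave 379 genes.

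The PHx changes differed between genotypes, by camera's test of the difference, for 12 lists. The adjusted p were 2.66e-09 for fatty acid oxidation, 5.60e-06 for other classical PPARα targets, 1.65e-04 for lipid droplet and fat uptake, 2.91e-04 for fatty acid and triglyceride synthesis, 6.11e-04 for gluconeogenesis and 6.11e-04 for oxidative phosphorylation. They were 0.00579 for xenobiotic metabolism, 0.0204 for the circadian clock, 0.0315 for cholesterol synthesis, 0.0315 for Kupffer cell and macrophage, 0.0339 for liver sinusoidal endothelial cell and 0.0367 for pancreas. With an estimated correlation none of them passed, the adjusted p running from 0.159 to 0.790.

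Single arrays stood apart from the other 3 of their group for 19 of 400 gene-and-group sets tested (4.75%) and for 5 of 144 list-and-group sets (3.47%), against about 5% by chance. The gap to the nearest array, as a share of the group's range, is given for each. In PHx PparaΔHep livers array 1 stood apart in Jun (0.924), Derl3 (0.854), Insig1 (0.853) and Cyp7a1 (0.836), with a Cyp7a1 level of 6.39 against 1.79 to 2.54 on the other 3 arrays. In PHx fl/fl livers array 1 stood apart in Acot2 (0.891) and array 3 in G6pc (0.902) and Snhg11 (0.919). In sham fl/fl livers array 2 stood apart in Pdk4 (0.927), array 1 in Tnfrsf12a (0.921) and the acute phase list (0.869), array 3 in the T and NK cell list (0.852) and array 4 in the sinusoidal endothelial list (0.860). In sham PparaΔHep livers array 1 stood apart in Sult1e1 (0.845) and Serpina7 (0.868), array 2 in Plin4 (0.852), Fgf21 (0.866) and Decr2 (0.900), array 3 in Clec4g (0.832), Crat (0.869), the growth factor and AKT list (0.870) and the autophagy list (0.844), and array 4 in Dnase1l3 (0.842), Nop2 (0.923) and Snhg11 (0.938).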

How the results depend on the processing

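The alternative restricted to protein-coding genes was chosen after seeing the data; the others were planned. No paired analysis was possible because the replicate numbers follow the order of the samples and pair nothing; the title numbers served as a block instead. The share of higher genes turned from 36.5% to 56.7% after cyclic loess and 56.3% over all probe sets in fl/fl livers, and from 45.8% to 53.7% and 61.4% in PparaΔHep livers. With cyclic loess the median of the hepatocyte markers also turned, from -0.13 to 0.04 and from -0.07 to 0.06. Other called lists shrank, such as oxidative phosphorylation (-0.16 to -0.00 and -0.29 to -0.09), autophagy (-0.24 to -0.07 and -0.31 to -0.13) and, in PparaΔHep livers, fatty acid oxidation (-0.39 to -0.19). With array medians subtracted these falls were larger instead, at -0.19 and -0.42 for oxidative phosphorylation and -0.27 and -0.44 for autophagy. For fatty acid oxidation in PparaΔHep livers the median was then -0.52. The cause was not tested. PHx changed 9868 genes in fl/fl and 9734 in PparaΔHep livers, against 6492 and 6318 without the dimmer genes, 18600 and 18600 over all probe sets, 5570 and 5820 at 0.01, 2336 and 2689 with the fold minimum and 5817 and 5959 among protein-coding genes; fewer or more tests or a stricter rule account for these by construction. Without 1 array they were 7711 to 10176 and 7720 to 10099. The correlation of the PHx changes was 0.870 among protein-coding genes and 0.909 to 0.937 without 1 array.

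Genotype changed 4 genes after sham, against 2 with array medians subtracted, 1 over all probe sets, 24 with array weights, 38 from the 8 arrays alone, 1 at 0.01 and 1 to 6 without 1 array. After PHx it changed 43, against 0 from the 8 arrays alone, 26 with the block, 15 at 0.01 and 14 to 127 without 1 array. For the difference the count of 0 became 0 to 2. The cause was not tested for the array weights, the median subtraction and the block. Fatty acid oxidation after sham lost its call with an estimated correlation (adjusted p = 0.403) and fry (0.149), and kept it without 1 array (6.21e-19 to 3.00e-10). Other targets after sham lost theirs with both (0.603 and 0.198) and in 3 of the leave-one-out fits (0.00676 to 0.12); the cause was not tested. Both lists kept their calls after PHx.

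Beside oxidation and other targets in the genotype comparisons, the lists called were 8, 12, 7, 9 and 12 for PHx in fl/fl, PHx in PparaΔHep, genotype after sham, genotype after PHx and the difference. Of these calls an estimated correlation ended 8, 12, 7, 8 and 12, fry 2, 1, 7, 7 and 12, and leaving out 1 array 5, 4, 6, 5 and 6. Of the lists not called, fry called 13, 10, 0, 0 and 0, and leaving out 1 array 2, 5, 4, 7 and 8. Cyclic loess ended the calls of 33 of 145 named genes for PHx in fl/fl and 16 of 138 in PparaΔHep livers. Signal close to the background limits the dimmer genes.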

Other observations

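The permutation test of the lipid droplet hypothesis was chosen after the result was seen.

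Genes of the circadian clock moved in both directions after PHx. Arntl, which encodes the activator BMAL1, fell by 1.67 ± 0.20 on the log2 scale in fl/fl livers and by 1.79 ± 0.20 in PparaΔHep livers (SE, 4 arrays per group), and its relative Npas2 fell by 1.07 ± 0.14 and 1.42 ± 0.14. The repressor genes Per1 and Per2 rose by 1.01 ± 0.19 and 1.20 ± 0.18 in fl/fl livers. Of 17 measured clock genes 3 rose and 3 fell in fl/fl livers (4 and 3 adjusted over the list alone; adjusted p = 0.464), and 2 rose and 5 fell in PparaΔHep livers (3 and 5 adjusted over the list alone; 0.665), where the median was 0.15 but the mean -0.13 and the direction of the test down. Among acute phase genes Lbp, which binds bacterial lipopolysaccharide, fell by 0.96 ± 0.16 and 1.08 ± 0.16 and Saa4 by 1.52 ± 0.27 and 1.38 ± 0.27, while the values of Saa1 were -0.16 ± 0.09 and -0.19 ± 0.09 (adjusted p = 0.195 and 0.122). In that list 3 of 27 rose and 11 fell in fl/fl livers (3 and 14 adjusted over the list alone; 0.104), and 3 rose and 10 fell in PparaΔHep livers (3 and 11; 0.0798). Lifr, a receptor of the IL-6 cytokine family, fell by 0.92 ± 0.19 and 1.03 ± 0.19. The value of Socs3, a feedback inhibitor of that pathway, was -0.51 ± 0.21 in fl/fl livers (adjusted p = 0.0675). In the IL-6 and STAT3 list, 1 of 19 genes was higher and 7 lower in fl/fl and 1 higher and 5 lower in PparaΔHep livers (1 and 7, and 1 and 6, adjusted over the list alone; 0.429 and 0.218). Growth factor and AKT genes fell in 6 of 23 in fl/fl livers and rose in 1 and fell in 7 in PparaΔHep livers (6, and 2 and 7, adjusted over the list alone; 0.426 and 0.0654), with Hgfac, which activates the hepatocyte growth factor, at -0.77 ± 0.13 and -1.06 ± 0.13 and the insulin signalling gene Irs1 at -0.94 ± 0.24 and -1.35 ± 0.24.

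The remaining lists were not called after PHx in fl/fl or PparaΔHep livers, except that fatty acid and triglyceride synthesis and bile acid synthesis were called in the latter. In fl/fl livers fatty acid and triglyceride synthesis had 1 of 20 members higher and 9 lower (2 and 10 adjusted over the list alone; adjusted p = 0.129), among them Mlxipl, which encodes the carbohydrate response factor ChREBP, at -1.65 ± 0.20, and bile acid genes 1 of 22 higher and 10 lower (2 and 11; 0.132). The mean of the bile acid list changed by -0.58 in fl/fl and -0.59 in PparaΔHep livers, and the call in one genotype alone does not show that they differ (exact permutation p = 0.962). Stellate cell markers fell in 4 of 10 in each genotype (4 and 4 adjusted over the list alone; 0.189 and 0.0913), with Lrat, which stores vitamin A, at -1.10 ± 0.28 and -1.82 ± 0.28. Monocyte markers fell in 2 and 3 of 8, with 1 higher in PparaΔHep livers (2, and 3 with 1 higher, adjusted over the list alone; 0.774 and 0.565), and Lyz2, of macrophages and neutrophils, stood at -0.95 ± 0.22 and -1.14 ± 0.22. The adjusted p in fl/fl and PparaΔHep livers were 0.294 and 0.153 for p53 targets, 0.189 and 0.475 for gluconeogenesis, 0.588 and 0.152 for glycolysis, 0.153 and 0.904 for xenobiotic metabolism and 0.966 and 0.504 for NRF2 targets. They were 0.933 and 0.218 for female-biased genes, 0.564 and 0.218 for neutrophils, 0.185 and 0.707 for T and NK cells, 0.129 and 0.290 for B cells, 0.966 and 0.346 for cholangiocytes, 0.185 and 0.475 for erythroid and blood genes, 0.966 and 0.190 for pancreas and 0.527 and 0.218 for adipocytes. Ribosome biogenesis, called in fl/fl livers, was not called in PparaΔHep livers (0.306), and other targets and lipid droplet genes were not called there either (0.428 and 0.661).

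A hypothesis is that PPARα of hepatocytes may contribute to the rise of some lipid droplet genes after PHx. Plin2 and Cidec still rose by 0.94 ± 0.14 and 1.11 ± 0.38 in PparaΔHep livers. If the gene was disrupted as labelled, hepatocyte PPARα is thus not needed for all of the rise. The Ppara probe set did not settle the labels, and a technical difference that follows the operation cannot be told apart from PHx. The droplet list as a whole was not called in fl/fl livers (camera adjusted p = 0.185). The mean of the 25 droplet genes changed by 0.37 after PHx in fl/fl and by -0.02 in PparaΔHep livers, a difference of -0.39 (SD over regroupings 0.17). In an exact two-sided permutation of genotype within each operation (4900 regroupings) this gave p = 0.0135, and 0.220 after adjustment over 36 lists. The permutation assumes no genotype effect after either operation, so it does not test equal PHx changes alone. The difference fails that correction and was found in the same data, and 3 of the genes (Plin2, Cidea and Fitm1) also stand in the list of other targets. Pancreas markers had a smaller p (0.00449) and the clock a similar one (0.0184). With array medians subtracted the median difference went from 0.13 to 0.03 for pancreas markers, -0.13 to -0.23 for the clock and -0.23 to -0.33 for droplet genes. All lists shift by the same amount in that setting, so it does not set the droplet genes apart. After cyclic loess the values were 0.09, -0.11 and -0.25. The structure of the PHx arrays that other splits point to stays open, and the fat content of the livers was not analysed here.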
